A study of Mus musculus with 4 samples.

How the data were processed

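RNA of mouse CH10T1/2 cells, an embryonic fibroblast line that can be turned towards cartilage, bone, fat or muscle, was measured on 4 Affymetrix Mouse Genome 430A 2.0 arrays, 1 array per group. The labels give stable transfection with either the wild-type PTHR1 (the receptor for PTH and PTHrP, called the WT line below) or its R150C variant (the R150C line). Cells of each line spent a night in serum-free medium and then received 1e-07 M PTHrP or carrier for 1 h. For the WT control array the sample's own labels say only control, and the series text gives carrier.

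The deposited value of each probe set is a fluorescence intensity on a linear scale, called signal below, which the authors obtained with Affymetrix Expression Console, per the submitters' processing notes. The version and the summarisation algorithm are not given in the sources used here, and the table has no detection calls. The mean signal after trimming 2% of the probe sets at each end was 150.1 in every array, so the deposited values carry a global scaling. The median over probe sets other than controls still differed, at 52.2 and 44.7 in the WT line (control and PTHrP) and 48.1 and 45.8 in the R150C line.

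Each array held 22690 probe sets, 64 of them Affymetrix controls, which were left out of every gene result. Of the others, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none or were not listed. Entrez identifiers matched the mouse gene table (assembly GRCm38.p6, used for names only) for 20351 of the probe sets with 1 symbol. No coordinates are given, since the files name no genome build. The brightest probe set by mean log2(signal + 16) over the 4 arrays stood for each of 12393 genes, and 6197 genes with that mean at or above its median over genes were kept. Turned back from the log scale, that filter lies at a signal of 62.6.

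Differences are on the scale log2(signal + 16), after subtraction of each array's median over all probe sets that are not controls, and understate the change of dim genes. This centring, fixed before the data were examined, left the kept genes with a median difference of 0.22 for PTHrP in the WT line, 0.05 for PTHrP in the R150C line, 0.08 between the lines in control medium and -0.07 between them under PTHrP. Bright and dim genes therefore shifted differently between arrays. The WT PTHrP difference of any kept gene should be read against 0.22. A second centring, on the kept genes, was added after the data were seen, which left median differences between -0.07 and 0.03.

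With 1 array per group, the 4 single contrasts and the difference between the PTHrP responses are values with no test, counted at 2-fold. The spread of a difference between a pair of arrays, estimated from the departure from additivity over the kept genes, was 0.23 (SD, log2). Effects common to both lines or to both treatments were tested with limma's additive model (receptor and treatment), with Benjamini-Hochberg adjustment at 0.05. Its sole error is the departure from additivity, with 1 residual degree of freedom. Because of the shift above, limma gave every gene the same standard error of 0.19 under the main centring, and its smallest adjusted p there (6.75e-122) overstates the precision. For named genes the text gives the largest adjusted p over 4 scalings: the main one, the deposited values without centring, quantile normalization and centring on the kept genes. A gene is called higher or lower between the lines below only where its adjusted p was under 0.05 in each of these, a rule added after the data were seen. The p-values measure the spread between these arrays alone. Receptor and line cannot be told apart, since each receptor is represented by 1 transfected line.

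The 27 gene lists, with 779 different genes in all and some genes in several lists, were written before the data were examined. For lists with at least 5 kept genes the median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. A list stands apart below when it lies outside the central 95% of the random lists, a bound chosen after the data were seen, as was the minimum of 5 genes. Counts adjusted over the list alone use the main centring. Of 22 lists with at least 5 kept genes, 1.1 per contrast would stand apart by chance if the members of a list varied independently. Members can move together within an array, and some lists share genes, so the number by chance may be higher. Of 60 simulated lists of 20 genes, each gene drawn independently, 93.3% lay inside the central 95% when unchanged, and 100.0% above it after a shift of 0.3 (log2). The limma step was tested on simulated data for the 6197 kept genes: it called 61 of 67 genes changed 2-fold between the receptors and 65 of 67 changed 2-fold by PTHrP, against 8 and 20 of 67 changed 1.5-fold, and of 5997 unchanged genes it called 0 and 5. The simulated noise was additive, with 1 variance for all genes as under the main centring, and without the shift between bright and dim genes. These rates therefore assume the equal error that is in doubt above and do not test it.

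Named genes followed a rule fixed before the data were examined. It took Pth1r, Igfbp3, Gli1, Gli2, Gli3, Ptch1 and Hhip at any level, and per direction 10 genes with the largest smaller difference over both lines or both treatments. It also took 5 genes per direction in each single contrast and in the difference between the responses, and up to 4 members of each list. Predicted genes and clones were passed over in the naming alone. Genes named outside the rule are said to be so.

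The alternatives changed the centring, the filter (none, or the 75th percentile), the choice of probe set (mean of all), the pseudocount (1 or 64), the fold threshold (1.5 or 3), limma's prior variance, its model and its threshold (0.1), and the matching and summary of the random lists. Programs were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.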

Results

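Transcripts were measured on 4 arrays in a 2 by 2 layout: CH10T1/2 cells carrying the WT or the R150C receptor, each with control medium or PTHrP for 1 h, with 1 array per group. The R150C variant comes from enchondromas, benign cartilage tumours, per the labels, and the series title concerns the regulation of IGFBP-3 by Gli signalling in cartilage tumours. Values of single arrays have no replicate error, and the number of arrays limits the precision of everything below. Pearson correlations between arrays, across all probe sets, ran from 0.969 (WT control with R150C control) to 0.985 (both R150C arrays). The 3' to 5' signal ratio of the Gapdh control probe sets was 0.845 in the WT control array, 1.17 in the WT PTHrP array, 0.991 in the R150C control array and 1.21 in the R150C PTHrP array.

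The transfected receptor could not be followed. The Pth1r probe set read 3.9 and 3.3 in the WT line (control, PTHrP) and 3.4 and 3.2 in the R150C line, close to the floor of the array, and need not detect the transfected cDNA, whose species is not given in the sources used here. Igfbp3, which encodes a secreted binding protein for insulin-like growth factors, read 24.2 and 23.6 in the WT line against 1.9 and 14.4 in the R150C line. All 4 values lie below the filter level of 62.6, which is a mean on the log2(signal + 16) scale turned back to signal. Ptch1, the hedgehog receptor and a direct target of Gli proteins, read 112.1 and 110.4 in the WT line and 28.0 and 36.7 in the R150C line, a difference of -1.45 in control medium and -1.29 under PTHrP (log2). On that scale its mean stands for a signal of 62.3, just under the filter, so it was not tested. The difference of Ptch1 over both media was -1.37, and -0.63 with the mean of all its probe sets. Gli1 read 32.7, 38.7, 19.2 and 22.7 in the same order, Gli2 66.0, 58.1, 30.9 and 28.1, and Gli3 48.5, 22.1, 24.2 and 18.1. Hhip, another Gli target, stayed between 1.7 and 6.5 in the 4 arrays.

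**Figure D1:**
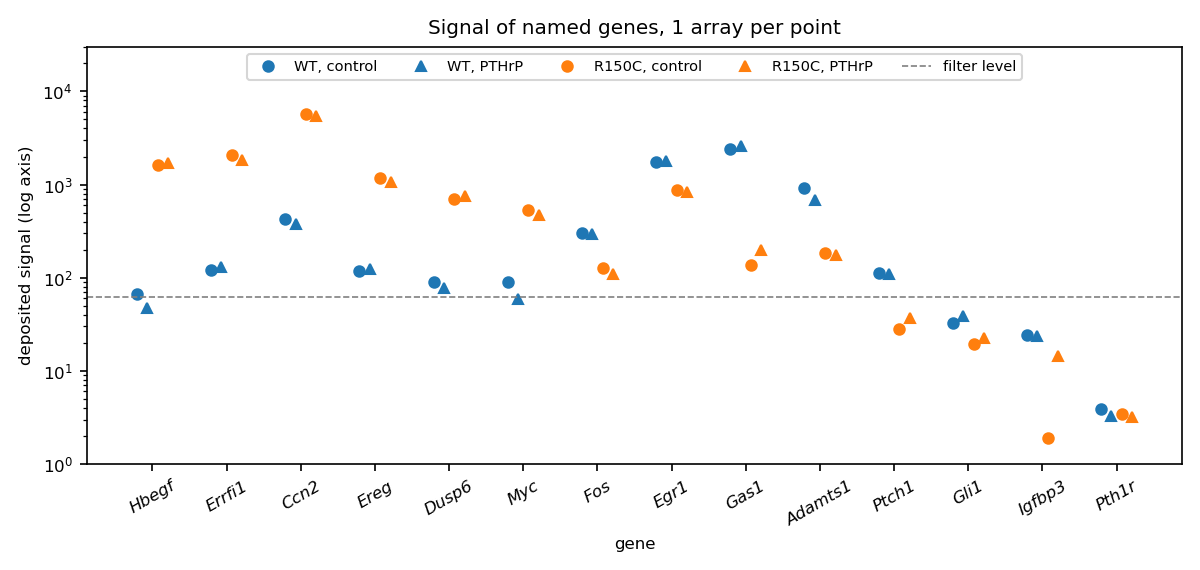
Deposited signal (log axis) of 14 genes in each of the 4 arrays, with 1 point per array, blue for the WT line, orange for the R150C line, circles for control and triangles for PTHrP; the dashed line is the filter level of 62.6. Hbegf reads 66.6 and 46.9 in the WT line and 1629.8 and 1688.7 in the R150C line, while Gas1 runs the other way.

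The comparison of the R150C with the WT line asked which transcripts differ between cells carrying the variant and cells carrying the normal receptor. Hbegf, a membrane-bound ligand of the EGF receptor, was higher in the R150C line by 4.41 in control medium and 4.73 under PTHrP (log2). Ereg, another ligand of that receptor, was higher by 3.27 and 2.93, and Errfi1, a feedback inhibitor of it, by 4.01 and 3.66. Ccn2, a matricellular growth factor, was higher by 3.77 and 3.75, and Dusp6, a phosphatase that switches off ERK, by 2.84 and 3.01. Gas1, a membrane protein that binds hedgehog ligands and is known as a growth arrest gene, was lower, with differences of -3.90 and -3.64.

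Fitted over both treatments with limma, Hbegf was higher by 4.57 (SE 0.19), Errfi1 by 3.83 (SE 0.19) and Ccn2 by 3.76 (SE 0.19), with largest adjusted p over the 4 scalings of 3.68e-06, 6.76e-06 and 6.76e-06. The hyaluronan synthase gene Has2 (3.13), Ereg (3.10), Noct (3.03), Dusp6 (2.93), Sema7a (2.73), Myc (2.56) and the angiogenic factor gene Vegfa (2.55) completed the 10 highest by the naming rule, each with a largest adjusted p of 6.05e-05 or less by limma. At the other end stood Gas1 (-3.77, limma's largest adjusted p 1.01e-05), Trp53inp1 (-2.37), the extracellular protease gene Adamts1 (-1.99), the Wnt agonist gene Rspo2 (-1.65), Trib3 (-1.64) and Dusp1 (-1.61). Ackr3 (-1.51), Txnip (-1.39), Tob1 (-1.35) and Zfp503 (-1.33) followed, with a largest adjusted p of 0.001 or less by limma. Gas1 stood at -2.11, Trp53inp1 at -1.39 and Trib3 at -1.09 with the mean of all probe sets of a gene.

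By lists, the growth factor immediate early genes stood out most. Their median difference over 27 kept members was 1.56 in control medium and 1.48 under PTHrP, each above 100% of matched random lists. Of the 27, 21 were higher in the R150C line, 2 were lower and 4 did not pass, whether adjusted over all genes or adjusted over the list alone. The 2 lower members were Fos (-1.06 and -1.33) and Egr1 (-0.91 and -1.12), both classic early genes, named here after their values were seen, while their relatives Fosl1 (2.5 and 2.15) and Egr2 (2.15 and 1.54), picked in the same way, were higher. The cAMP and CREB early response list had a median of 0.45 and 0.57 over 15 members, at the percentiles 99.98 and 100, the first of which was 92.39 without the filter. In it 7 members were higher, among them Has2, Lif (2.74 and 2.17) and the prostaglandin synthase gene Ptgs2 (2.10 and 2.11), and 3 were lower, among them Dusp1 (-1.48 and -1.73); adjusted over the list alone the counts were 9 and 3. Cytokines, chemokines and NF-kB targets had medians of 0.70 and 0.44 over 12 members, both at the percentile 100. In that list 6 members were higher, with Ccl2 at 1.76 and 1.78 and Csf1 at 2.00 and 1.76, and 1 was lower, counts that did not move when adjusted over the list alone. The cytokine list and the cAMP and CREB list share genes, Lif among them, so their standings are not independent.

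Other groups were mixed. Of 30 fibroblast and extracellular matrix genes 6 were higher, among them Ccn2, Ccn1 (1.87 and 1.48), Thbs1 (0.87 and 1.64) and Timp1 (1.08 and 0.51), and none was lower. Of 11 Wnt, BMP and Notch feedback targets, the TGF-beta inhibitor gene Smad7 (2.23 and 2.70), Ccn4 (1.56 and 1.46) and Id1 (1.10 and 1.19) were higher and Id2 (-0.99 and -0.89) was lower; the list stood at the percentile 97.63 in control medium (95.53 to 99.97 over the alternative settings) and 59.5 under PTHrP. Of 16 p53 targets 4 were lower, among them Trp53inp1 and Sesn2 (-1.03 and -1.44), and 2 were higher, one of them Plk2 (1.02 and 0.84); the list stood low in control medium, at the percentile 0.96 (37.47 with the filter at the 75th percentile), and at 10.71 under PTHrP. Among 26 amino acid and ER stress genes Trib3, Sesn2 and Herpud1 (-0.88 and -0.96) were lower and Atf3 (1.05 and 0.77) was higher. Of 21 hypoxia and glycolysis genes Vegfa, the hexokinase gene Hk2 (1.47 and 1.03) and the glucose transporter gene Slc2a1 (0.79 and 1.10) were higher, and Ndrg1 (-0.41 and -0.73) was lower. Of 9 homeodomain and position genes Twist1 (0.74 and 0.49) and Twist2 (0.79 and 0.46) were higher, while Hoxa5 (-1.05 and -0.70) and Meis2 (-1.12 and -1.04) were lower. Of 9 hedgehog pathway genes Snai1 (1.41 and 1.47) and Tnfrsf11b (1.34 and 1.05) were higher and Gas1 was lower. The list's median stood at the percentiles 94.01 and 26.86; over both media the median stood at 72.36 and the mean at 1.37. The low mean rests on Gas1 (-3.77), the 1 member at least 2-fold lower over both media, against 2 at least 2-fold higher.

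Of 36 cell cycle genes Kif11 (-0.74 and -0.59) alone was lower under each scaling, yet the list's median lay low in both media, at the percentiles 0.09 and 2.37, the latter from 0.72 to 3.22 over the alternative settings. Oxidative phosphorylation genes (46) and cytosolic ribosomal proteins (33) had no member called; their medians, -0.30 and -0.30, stood low under PTHrP, at the percentiles 0.02 and 1.28, but not in control medium, at 16.93 and 8.62. Over the alternative settings the ribosomal percentile under PTHrP ran from 0.04 to 83.18, the latter after quantile normalization. Of 20 apoptosis regulators Cflar (1.65 and 1.19) was higher. Of 14 heat shock genes Bag3 (0.99 and 0.56) was higher and Hspa1b (-0.99 and -0.62) lower. Dhcr7 (-0.70 and -0.82) was lower among 19 cholesterol synthesis genes, a list that stood high under PTHrP (percentile 99.88, but 93.91 by the mean of the list) and not in control medium (14.72), and Irf1 (-0.64 and -0.63) among 8 interferon response genes. Tnnt2 (0.76 and 1.58) was higher among 7 skeletal and smooth muscle markers, whose median stood at the percentiles 99.98 and 98.82, the second from 81.14 without the filter to 99.58. Prkar1b (0.72 and 0.69) was higher among 16 genes of PTHrP receptor and Gs signalling, and Tnfrsf11b among 9 osteoblast markers, a list at the percentile 2.26 under PTHrP, but from 1.47 to 37.57 there over the alternative settings. No member passed among 6 adipocyte markers, 6 genes of the IGF axis or the 3 kept chondrocyte markers, where the cartilage regulator Sox9 differed by 0.29 and -0.38. Adjusted over the list alone, the counts of higher and lower members were 7 and 1 for matrix genes, 2 and 3 for hedgehog genes, 2 and 3 for position genes and 3 and 2 for apoptosis regulators. They were 3 and 0 for muscle markers, 3 and 0 for receptor and Gs signalling, 0 and 2 for cell cycle genes, 1 and 1 for cholesterol synthesis and 1 and 0 for endothelial markers, and in the remaining lists equal to the counts above. These counts use the main centring, whereas those above required all 4 scalings. Adjusted over all genes under the main centring, the muscle, Gs signalling, cell cycle and cholesterol counts were the same as over the list alone. In that way they were 7 and 0 for matrix genes, 2 and 1 for hedgehog genes and 2 and 2 for position genes. Apoptosis regulators had 3 and 1, and endothelial markers 0 and 0. With the mean of all probe sets the difference over both media fell from 2.46 to 1.36 in Lif, from 1.88 to 1.05 in Csf1, from 1.42 to 0.82 in Cflar, from 0.71 to 0.05 in Prkar1b and from -0.94 to -0.60 in Id2. Of the markers of macrophages, endothelium, epithelium and neurons, 6 of 64 reached the filter and none passed limma's test over all genes; their median signal over all 64 was 21.5 and 16.3 in the WT line and 22.7 and 19.4 in the R150C line.

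**Figure D2:**
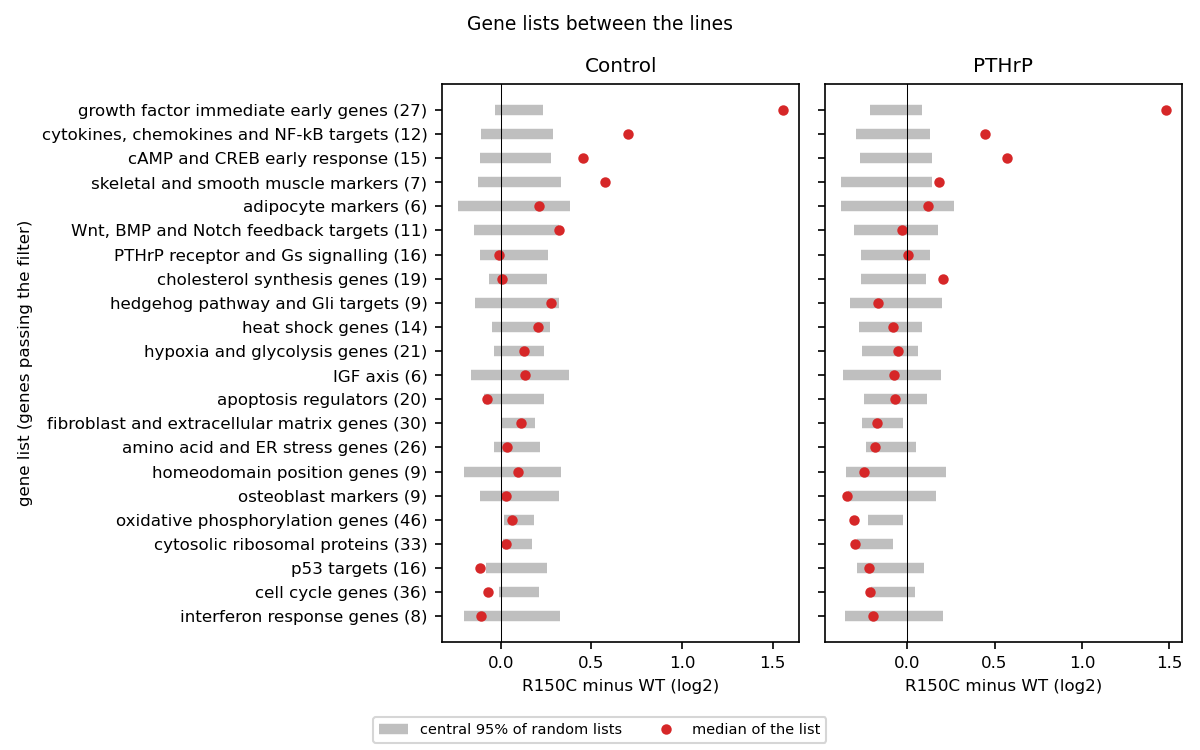
Median log2 difference between the lines (R150C minus WT) of each gene list with at least 5 kept genes, in control medium (left) and under PTHrP (right); red points are the medians, grey bars the central 95% of matched random lists, and the number of kept genes is in parentheses. The growth factor immediate early genes stand at 1.56 and 1.48, far to the right of their bars.

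In control medium 178 of the 6197 kept genes were at least 2-fold higher in the R150C line and 35 at least 2-fold lower, and under PTHrP 134 and 45. Without centring the control counts were 139 and 50, and centred on the kept genes 126 and 60. These differences share no array, and correlated across genes with r = 0.677, where genes are not independent replicates. At 1.5-fold, 242 genes were higher in both media against 32.9 for independent lists, and 91 lower in both against 11.3; centred on the kept genes these counts were 208 and 134. limma called 466 genes higher and 237 lower over both treatments, and 313 and 178 under each of the 4 scalings. Of 73 genes at least 2-fold apart in control medium by their brightest probe set and with another kept probe set, 71 had the same sign in the second one, and 60 of 62 did under PTHrP.

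**Figure D3:**
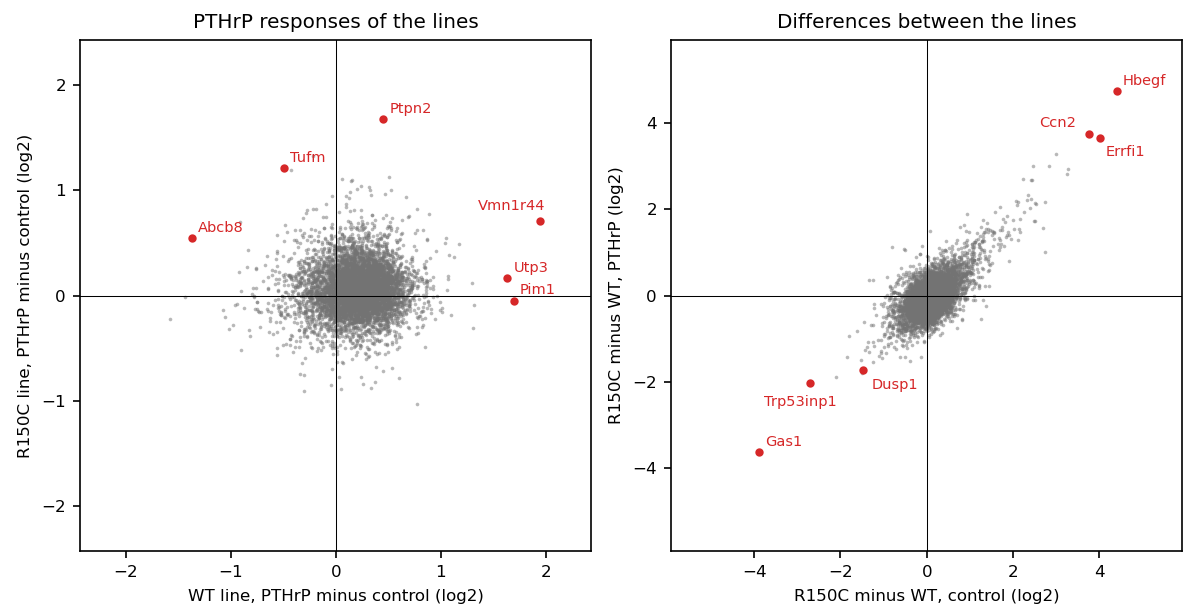
Log2 differences of the 6197 kept genes, 1 point per gene: left, PTHrP minus control in the R150C line against the WT line; right, R150C minus WT under PTHrP against control medium, with some named genes in red. The left cloud has r = 0.048 and the right one r = 0.677; the left cloud lies to the right of 0 by the median shift of 0.22 that the main centring leaves.

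The PTHrP comparison in the WT line asked what 1 h of ligand does through the normal receptor. Early response genes of cAMP and CREB, the pathway this receptor drives through Gs, did not stand apart: the median of 15 of them was 0.22, equal to the shift of all kept genes and at the percentile 51.82 of matched lists. Per1, a clock gene with CREB sites, differed by 0.47, Bdnf by 0.72, Vip by 0.74 and the salt-inducible kinase gene Sik1 by -0.48. Another probe set of Bdnf above the filter did not have the same sign in this contrast. The largest differences upwards were in Vmn1r44 (1.94), Pim1 (1.69), Utp3 (1.63), Rnf114 (1.32) and Slc25a20 (1.31), and downwards in Gid4 (-1.44), Abcb8 (-1.37), Trim35 (-1.07), Lsm12 (-1.06) and Srsf5 (-1.02). Pim1 rests on a signal of 9.6 in the control array and 57.7 after PTHrP, and Vmn1r44 on 26.2 and 128.4. With the mean of all probe sets Pim1 fell to 1.03, Slc25a20 to 0.75, Rnf114 to 0.17, Abcb8 to -0.41 and Gid4 to -0.04, and of 7 genes 2-fold changed and with another kept probe set 5 had the same sign in it. Oxidative phosphorylation genes had a median of 0.43, above 100% of matched lists, with Ndufb7 at 0.83 and Ndufs8 at 0.83. Cholesterol synthesis genes (-0.05, percentile 0.00), genes of receptor and Gs signalling (-0.01, percentile 0.39), cell cycle genes (0.14, percentile 0.73) and growth factor immediate early genes (0.14, percentile 2.4) lay below matched lists. Over the alternative settings the last 3 ran from 0.22 to 4.06, from 0.38 to 15.01 and from 1.08 to 12.33. The count at 2-fold was 17 higher and 6 lower, but 7 and 16 without centring, 10 and 11 after quantile normalization and 6 and 18 when centred on the kept genes.

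In the R150C line the median of the cAMP and CREB early response genes after PTHrP was 0.01, at the percentile 23.86, with Per1 at 0.97 (signal 55.5 and 118.7) and Sik1 at -0.21. Ptpn2 (1.68), a phosphatase gene, Cklf (1.32), Tufm (1.21), Lyrm2 (1.195) and Caprin1 (1.13) had the largest differences upwards, and Cysrt1 (-1.03), Fer (-0.91), Hoxa9 (-0.89), Flcn (-0.88) and Cluap1 (-0.85) downwards. With the mean of all probe sets Ptpn2 fell to 0.28, Cklf to 0.33, Tufm to 0.15, Lyrm2 to 0.68, Caprin1 to 0.03, Fer to -0.43 and Flcn to -0.29, and of 8 genes 2-fold changed and with another kept probe set 6 had the same sign in it. Growth factor immediate early genes lay low, with a median of -0.11 at the percentile 0.00, as did amino acid and ER stress genes (-0.06, percentile 0.51) and fibroblast and matrix genes (-0.03, percentile 1.60), while cholesterol synthesis genes lay high (0.17, percentile 98.08). Over the alternative settings these percentiles ran from 0.01 to 4.61, from 0.37 to 37.99, from 0.01 to 4.23 and from 93.83 to 98.29, in the same order. The count at 2-fold was 13 higher and 1 lower. The 9 hedgehog pathway genes had medians of 0.28 in the WT line and 0.18 in the R150C line, at the percentiles 71.26 and 93.62, and the 6 genes of the IGF axis 0.09 and -0.06, at 4.33 and 7.19, the first of which was 2.29 after quantile normalization. The other lists lay inside the central 95% in both lines.

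The responses of the lines to PTHrP correlated across genes with r = 0.048. Within 1 response, the 2 brightest kept probe sets of a gene correlated with r = 0.193 in the WT line and 0.065 in the R150C line. At 1.5-fold 11 genes were higher in both lines, against 6.14 for independent lists, and 0 lower in both; without centring these counts were 3 and 1, and centred on the kept genes 3 and 2. No gene was 2-fold changed the same way in both. The genes with the largest common difference upwards included Vmn1r44 (1.94 and 0.71), Dlx2 (0.78 and 0.82), Hip1r (0.88 and 0.77), Lrp6 (0.70 and 0.75), Ip6k1 (0.67 and 0.94) and Pqbp1 (0.69 and 0.75), and downwards Prkar2a (-0.56 and -0.57), Crim1 (-0.90 and -0.52), Smad5 (-0.56 and -0.50) and Slc41a3 (-0.51 and -0.47). With the mean of all probe sets Lrp6 turned to -0.19 in the WT line and fell to 0.42 in the R150C line, Smad5 stood at -0.18 and -0.15, Crim1 at -0.51 and -0.20, and Ip6k1 in the WT line at 0.16. Under that setting Slc41a3 in the WT line stood at -0.14, and in the R150C line Slc41a3 at -0.27, Ip6k1 at 0.32, Hip1r at 0.36 and Pqbp1 at 0.19. limma's additive fit called 22 genes higher and 3 lower under the main centring, 1 without centring, and 0 after quantile normalization or when centred on the kept genes, where 331 and 345 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.871 and 0.564. Over both lines the growth factor immediate early genes lay low (percentile 0.01). Hedgehog pathway genes lay high (0.40, percentile 99.99), although the percentile was 55.22 with the mean of all probe sets and 51.33 without the filter. Neither line alone stood apart by the median, but by the mean of the list both did (97.74 WT, 98.66 R150C), and R150C did with the stricter filter (97.78) and a pseudocount of 64 (97.66). In this list 3 genes were higher by limma when adjusted over the list alone, and 0 over all genes. Its 9 kept genes include neither the direct response genes Ptch1, Gli1 and Hhip nor Gli2 and Gli3, which all lay under the filter. The list's standing therefore does not show a hedgehog response to PTHrP. Under the main centring limma called 1 member each of the cAMP and CREB, osteoblast and muscle lists higher, whether adjusted over all genes or over the list alone, and 1 gene of receptor and Gs signalling lower over the list alone. No list had a member called under each of the 4 scalings. Oxidative phosphorylation genes lay high in the mean of the lines (percentile 99.39), which rests on the WT line, since they stood at 44.52 in the R150C line. Heat shock genes lay low in that mean (1.9, but from 1.63 to 11.14 over the alternative settings).

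The difference between the responses, R150C minus WT, asked whether the variant changes the effect of PTHrP. It was largest upwards in Abcb8 (1.92), Tufm (1.70), Lyrm2 (1.62), Gaa (1.62) and Cklf (1.54), and downwards in Cysrt1 (-1.80), Pim1 (-1.74), Slc25a20 (-1.62), Utp3 (-1.47) and Rnf114 (-1.41). With the mean of all probe sets Rnf114 turned to 0.12, and Abcb8 stood at 0.81, Tufm at 0.41, Lyrm2 at 0.93, Gaa at 0.44, Cklf at 0.15 and Slc25a20 at -0.93. Of 17 genes 2-fold apart and with another kept probe set 12 had the same sign in it. At 2-fold 25 genes were more positive in the R150C line and 40 more negative, a split that turned to 40 and 21 without centring, 38 and 30 after quantile normalization and 42 and 19 when centred on the kept genes. Cholesterol synthesis genes (0.05, percentile 99.35) and genes of receptor and Gs signalling (0.08, percentile 98.45) lay above matched lists, as did cell cycle genes (-0.06, percentile 98.17), and oxidative phosphorylation genes (-0.32, percentile 2.38) and matrix genes (-0.36, percentile 2.45) below. Over the alternative settings these percentiles ran from 97.38 to 99.98, from 91.71 to 99.07, from 90.26 to 99.46, from 0.01 to 2.84 and from 0.1 to 28.2, in the same order. This contrast uses every array once and leaves nothing to estimate an error from.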

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

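Chosen after the results were seen were the rule for which genes of opposite sign to list, the share of each array in the disagreement between probe sets, the resampled range of r among the brightest genes, and the demand that its bound hold under other settings. The tests of r among the brightest genes and of the ratio of that disagreement were set before their values were seen. With 1 array per group there was no test for an outlying array.

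In 9 of the genes named for the difference between the PTHrP responses, the difference after PTHrP had opposite signs in the lines under each of the 4 scalings. Genes chosen for a large difference of responses tend to have opposite signs by that choice. In Pim1 the R150C value was only -0.05, and in Cklf the WT value was -0.22, both within the SD of 0.23. Such signs do not show that PTHrP moved a gene in opposite directions. The difference between responses (R150C minus WT, log2) was 1.92 in Abcb8, 1.70 in Tufm, 1.62 in Lyrm2, 1.62 in Gaa and 1.54 in Cklf. It was -1.80 in Cysrt1, -1.74 in Pim1, -1.62 in Slc25a20 and -1.41 in Rnf114. Each rests on 1 array per group, and none of these differences was tested. With the mean over each gene's probe sets the difference was 0.81 in Abcb8, 0.41 in Tufm, 0.93 in Lyrm2, 0.44 in Gaa, 0.15 in Cklf, -1.29 in Cysrt1, -1.19 in Pim1 and -0.93 in Slc25a20, and it turned to 0.12 in Rnf114. Among all kept genes 3 differed at least 1.5-fold after PTHrP in opposite directions: Cysrt1 (0.77 in the WT line, -1.03 in the R150C line), Gaa (-0.91 and 0.70) and Plaat3 (0.61 and -0.79), the last picked after its values were seen. This count was 5 without centring, 5 with the mean of all probe sets, 8 with a pseudocount of 1, 1 with the filter at the 75th percentile, 88 without a filter and 0 at 2-fold. At 1.5-fold 349 of the 6197 kept genes were higher and 50 lower in the WT line, and 109 and 24 in the R150C line. Independent lists of these sizes would also hold a few genes of opposite direction, so the count of 3 is no sign of opposite responses.

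Outside the gene results, 800 probe sets with several symbols or none passed the filter. Of these, 11 differed at least 2-fold between the lines the same way in both media, 9 higher and 2 lower in the R150C line.

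The responses of the lines to PTHrP correlated across genes with r = 0.048. Among the kept genes above the 75th percentile of their brightness r was 0.048 as well, with a central 95% from -0.013 to 0.099 when genes were resampled. That lay under 0.1, the bound set beforehand as speaking against array noise hiding a common response. With the mean of all probe sets of a gene r among the brightest was 0.123, over that bound. The bound cannot decide, since noise alone also lowers r. Probe sets of 1 gene on the same arrays correlated in these bright genes with only r = 0.275 for the WT response and 0.126 for the R150C response. Array noise therefore stays open. Probe sets of 1 gene disagreed 1.343 times as much (SD) in the WT as in the R150C response, and of the summed variance of that disagreement 37.8% fell on the WT control array. That ratio went the way set beforehand for poor RNA quality of that array. By the correlations above, however, probe sets were less alike in the R150C response. The larger disagreement therefore cannot decide whether the low relation comes from the WT control array. The Actb 3' to 5' ratio of the WT control array was 1.43, against 2.39, 2.13 and 2.31 in the WT PTHrP, R150C control and R150C PTHrP arrays. Its Pcx ratio was 1.06, against 3.37, 3.31 and 2.78 in the same order, but its Tfrc ratio of 2.74 lay among the others (2.52 to 3.55). The Tfrc and Pcx ratios rest on dim 5' signals, at most 27.5 and 41.4 in any array, so they weigh little. A true difference of the responses by receptor was not tested and stays open.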

How the results depend on the processing

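Centring on the kept genes and the count under each of 4 scalings were added after the data were seen, as were the tolerances used here for single genes (a move by 1 SD of a difference, 0.23, and a change of sign only where the main value was beyond 2 SD, 0.45). No paired analysis was possible because each group has 1 array, beyond the additive model itself, which compares PTHrP with control within each line. No array could be left out, since 3 arrays leave the additive model no residual degree of freedom. The cause of each change below was not tested, except that a stricter or looser filter or fold changes how many genes can pass.

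Counts at 2-fold were 23 (WT PTHrP), 14 (R150C PTHrP), 213 (lines, control), 179 (lines, PTHrP) and 65 (difference of responses). In that order they became 153, 135, 401, 377 and 534 without a filter, 8, 8, 119, 94 and 12 with the filter at the 75th percentile, and 6, 3, 116, 109 and 12 with a pseudocount of 64. At 1.5-fold they were 399, 133, 755, 708 and 671, and at 3-fold 3, 1, 58, 41 and 7. A pseudocount of 1 gave 57, 22 and 133 for the WT, R150C and difference counts. The R150C PTHrP count alone moved to 9 without centring, 7 with the mean of all probe sets and 9 when centred on the kept genes.

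Genes 1.5-fold the same way after PTHrP in both lines numbered 11, and 4 without centring, 3 after quantile normalization, 73 without a filter, 2 with the stricter filter, 34 and 0 with pseudocounts of 1 and 64, 5 when centred on the kept genes and 0 at 2-fold. The shared line differences, 333, became 525 without a filter, 168 with the stricter one, 214 with a pseudocount of 64 and 120 at 2-fold. limma's PTHrP calls fell from 25 to 1 without centring, 13 with the stricter filter and 0 after quantile normalization, when centred on the kept genes, without the receptor term and over the 4 scalings together. Its receptor calls, 703, moved past 1.5 times only with the stricter filter (351), and were 491 over the 4 scalings.

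Of 1872 values of named genes under the alternatives 1648 moved by less than 0.23, 222 by more, and 2 changed sign from beyond 2 SD, both with the mean of all probe sets: Lrp6 after PTHrP in the WT line (-0.19) and Rnf114 in the difference of responses (0.12). Another 41 changed sign from within 2 SD, 14 of them by a move of over 1 SD, such as Chd1 after PTHrP in the WT line (-0.41 to 0.07) and Cald1 between the lines (0.38 to -0.08). Dropping the centring or centring on the kept genes shifts all genes of a contrast alike. The largest such shift took the median from 0.22 to 0.03 (PTHrP, WT line). The 312 values under each of these settings thus could not move by 0.23. Under quantile normalization 312 stayed within 0.23 as well. Of the 222, 92 came from the mean of all probe sets, 91 from a pseudocount of 64 and 39 from a pseudocount of 1. Of 487 list percentiles 410 kept their side of the central 95%, 71 moved inside it and 6 outside it. Those centrings also shift a list and its random lists alike. The correlation of the line differences ran from 0.446 without a filter to 0.761 with the stricter one, and that of the PTHrP responses from 0.033 to 0.098. Levels near the floor, such as those of Igfbp3, Gli1 and Pth1r, limit what can be said of those genes.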

Other observations

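The tests in this part were chosen after the results were seen, except that of other cell types; the bounds of the YAP and hedgehog tests were also changed, and those of oxidative phosphorylation genes split, after their values were seen. The lists of ERK outputs and of YAP and TEAD targets were written after the differences were seen, so they are not independent evidence.

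Hbegf, Ereg and Errfi1 were among the 10 highest genes in the R150C line, and Dusp6 and Spry2 (1.69 in control medium and 2.05 under PTHrP), which restrain ERK signalling, were higher too, while Dusp1, another phosphatase of MAP kinases, was lower (-1.48 and -1.73). Il11 (signal 14.7 and 13.5 in the WT line, 99.0 and 66.9 in the R150C line) and Arc (5.0 and 5.8 against 100.8 and 82.0) lay below the filter on average and were not tested. Spry2, Il11 and Arc were picked after their values were seen.

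The higher level of growth factor immediate early genes in the R150C line was weighed against technical sources. Their lowest median difference over both media and 4 scalings was 1.437. These scalings left the median line difference of all kept genes between -0.07 and 0.08. The choice among them therefore does not account for the list's difference. Since it moved typical genes so little, this outcome was fixed beforehand and is no test of scaling. The median in the PTHrP pair was 0.949 of that in the control pair, although the WT control array, lowest of the 4 in its Gapdh, Actb and Pcx 3' to 5' ratios but not in that of Tfrc (2.74, others 2.52 to 3.55), enters the control pair alone. The Pcx and Tfrc ratios rest on dim 5' signals, at most 41.4 and 27.5 in any array. Markers of macrophages, endothelium, epithelium and neurons had a median signal of 21.0 over the R150C arrays, 1.11 times that in the WT arrays and far below the filter level of 62.6. A median pooled over these types could hide 1 of them. By type the medians ran from 11.4 (epithelium) to 29.0 (endothelium) in the R150C arrays, and from 12.4 (macrophages) to 29.8 (neurons) in the WT arrays. Macrophage markers read 12.4 in the WT and 21.4 in the R150C line under PTHrP, but 22.2 and 19.6 in control medium. These levels argue against a large share of cells of those types and no others. Skeletal and smooth muscle markers, a fate open to this line, stood high with the growth factor list (percentiles 99.98 and 98.82), and whether a share of cells on that path enters the difference was not tested and stays open. With 1 line per receptor, the receptor variant and any other difference between the lines (clone, density, passage) cannot be told apart.

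One hypothesis is that ERK output differs between the lines. Of 29 ERK output genes, 10 were kept and lay outside the growth factor list, and their median (1.61 in control medium, 1.42 under PTHrP) was above 100% of matched lists in both media; 8 of the 10 were higher under each scaling and none was lower. The list was written after the differences were seen, so its standing does not test the hypothesis. It goes with higher ERK output in the R150C line after a night without serum, yet Fos (-1.06 and -1.33) and Egr1 (-0.91 and -1.12), themselves ERK targets, were lower. Another hypothesis is that YAP and TEAD targets differ. Of 26 such genes 16 were kept, with a percentile of 100 in control medium and 97.56 under PTHrP, but 99.8 and 92.7 without the genes shared with the growth factor list. Under each scaling 5 of the 16 were higher and 0 lower, and of the 14 without the shared genes 3 and 0. Without the shared genes the list thus still stood apart in control medium but not under PTHrP, where the lists cannot be told apart.

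A further hypothesis is a lower hedgehog response in the R150C line. Of the 3 direct response genes Ptch1, Gli1 and Hhip, 1 (Ptch1, -1.45 and -1.29) was lower by over 0.5 in both media. Over both media Ptch1 differed by -1.37, but by -0.63 with the mean of all its probe sets. Gli1 differed by -0.38 and -0.53, and Hhip by 0.19 and 0.19 near the floor. By their mean log2(signal + 16) all 3 genes lie under the filter, Ptch1 just so (62.3 against 62.6 in signal units), and they were not tested, so this neither bears out the hypothesis nor excludes it.

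Oxidative phosphorylation genes stood above matched lists after PTHrP in the WT line (percentile 100) and not in the R150C line (44.52). Quantile normalization left them at the percentile 100, which argues against the scaling of the arrays. Between the lines they lay at 0.02 under PTHrP and at 16.93 in control medium, so the shift follows the WT PTHrP array and not the WT control array. The WT PTHrP array had the highest 3' to 5' ratios of the 4 for Actb (2.39), Tfrc (3.55) and Pcx (3.37), though the R150C control array was close to it (2.13, 3.25 and 3.31). Its Tfrc and Pcx ratios rest on dim 5' signals, of 5.1 and 23.8. Whether the shift belongs to the treatment, a response of the WT line, or to the single WT PTHrP array and its RNA was not tested and is open.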
